A study of Mus musculus with 4 samples.

How the data were processed

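Lung cells of allergen-challenged mice were digested, sorted for CD45.2 and run on 10x Genomics 3′ v3.1 chemistry with TotalSeq-A antibodies, with about 16000 cells loaded for 10000 emulsions, per the labels' protocols. The deposited matrices hold UMI counts per gene or antibody and cell barcode, not normalized. They were made with Cell Ranger 7.1.0 and 7.0.0 on the mm10 build, per the submitters' processing notes, and with Cell Ranger 7.0.0, per the file headers. The authors deposited barcodes already called as cells. Each matrix was given its genotype by the library prefix that its name shares with the library name in the sample description, and its antibody tags belong to the matching antibody library. No cell annotation was used. Which part of Plaur is deleted is not given in the sources used here.

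Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left out 80 WT-labelled and 61 KO-labelled barcodes. Doublets called by Scrublet within scanpy 1.11.5 (expected 8%) were removed per library, 261 (2.92% of filtered barcodes) and 454 (4.52%). Both libraries were clustered together without integration on log-normalized values (3000 variable genes without Plaur, sex-linked, mitochondrial, ribosomal and receptor variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 with the igraph method of scanpy), which gave 35 clusters. Names came from 25 fixed marker sets: a marker counted when found in at least 20% of a cluster's cells and at least 2-fold over other cells, and a name needed at least 3. Cluster 28 stayed unnamed (100 and 59 cells). Of the fixed symbols, 9 matched no symbol in the matrices and are not analysed here. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.

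With 1 library per genotype no test was run. UMIs were summed per library and class and given as CPM of the class sum with exact Poisson intervals. The log2 ratio of KO-labelled over WT-labelled has an exact conditional binomial interval and a share an exact Clopper-Pearson interval, all at 95% and for counting error only. A count of 0 was given a limit of 3 counts. The main classes are named classes with at least 150 kept cells in each library, at most 6, without T cells, which were compared by cluster. The genes named are, per main class, the 6 with the highest and the 6 with the lowest ratio by the interval bound nearest 0, at 100 or more UMIs over both libraries, without markers of other classes, mitochondrial, ribosomal, haemoglobin, receptor segment and sex-linked genes. No table used here says which predicted (Gm) genes are copies of ribosomal protein genes, so none was left out on that ground. Plaur, the genes of the antibody targets, and up to 2 highest and 2 lowest members of a described list at 50 or more UMIs were added. Of the list members taken by this rule, 1 gene was left out of the text and is not reported here. For each of 24 gene lists, the median log2 ratio of members with at least 20 UMIs (at least 5 members, 0.5 UMI for a member with 0 UMIs in 1 library) was placed among 10000 random lists matched in 20 expression bins. The lists of sex-linked, of substrain-variable, and of red cell and platelet genes had too few measured members in each main class. Antibody levels are mean UMIs per cell, as log2 ratio to the B cells of the same library. Marker sets, lists, the rule for named genes and the first group of alternatives were fixed before the data were examined. Which antibodies counted as above background, by 2-fold over B cells, was set afterwards, as were the limits for a marker to count and the eosinophil genes and number of them asked of a barcode.

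The interval method was tested on simulated counts. With 5990 genes at the neutrophil means, 95.2% of intervals held the true ratio, and the interval excluded 0 for 100% of genes changed by 1 on the log2 scale. With 3844 genes at the NK cell means the values were 95.1% and 98%. The simulation drew independent counts, as the interval itself assumes, so it checks the computation only. It holds counting error, no crowding of UMIs in few cells and no spread between animals. Crowding can exceed the intervals: the Ly-6C antibody difference in classical monocytes was -0.25 (interval -0.27 to -0.23). Without the 1% of cells with most UMIs it was -0.57.

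The first group of alternatives held at least 500 genes or at most 5% mitochondrial UMIs per cell, doublet calls kept, resolution 0.5, each library clustered alone, shares among cells other than neutrophils, TMM factors (edgeR 4.0.16) and DESeq2 1.42.0 size factors on the class sums, totals without mitochondrial, ribosomal and haemoglobin genes, each cell thinned to 1000 UMIs, other member minimums for lists, and for antibodies centred log-ratios, medians and raw means. In neutrophils thinning left out 106 WT-labelled and 177 KO-labelled cells. Chosen after seeing the data were clustering without genes within 10 Mb of Plaur, Hprt and interferon genes, weighting each cluster alike in both libraries, thinned list medians, leaving out the 5 cells with most UMIs of a gene, antibody levels with each cluster weighted alike, cDC2 with CCR7 dendritic cells and group 2 innate lymphoid with gamma-delta T cells pooled, and leaving out the 1% of cells with most UMIs of an antibody. Gene positions come from a RefSeq table of the same build, which held 81.6% of the gene symbols. TMM and DESeq2 factors moved all log2 ratios of neutrophils by 0.11 and 0.12, and those of classical monocytes by 0.11 and 0.12.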

Results

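Lung leukocytes of a mouse model of allergic airway inflammation were profiled by single-cell RNA sequencing together with 5 surface antibodies (CD11b, CD14, CCR3, Ly-6C and ST2) read out as sequence tags. Wild-type mice and mice lacking Plaur, the gene of the urokinase receptor uPAR, had been sensitized with ovalbumin and lipopolysaccharide on days 0 and 7 and then challenged with aerosolized ovalbumin on day 14. There was 1 RNA library with its antibody library per genotype, and the design names 8 mice per genotype, without saying how many contributed to each library. No difference below therefore has a replicate check, no test between genotypes was possible, and all intervals printed are 95% intervals that cover counting error only. The library labelled WT held 9024 barcodes with 42913843 gene UMIs, of which 8683 cells were kept with a median of 3208 UMIs. The library labelled Plaur KO held 10102 barcodes with 47442215 gene UMIs, of which 9587 cells were kept with a median of 2776 UMIs. They are called the WT-labelled and KO-labelled library here, because Plaur RNA was not absent from the latter, and every direction below rests on these labels.

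Plaur RNA was counted in both libraries, at 526 CPM (UMI counts scaled to the total of the cells summed) in the WT-labelled and 456 CPM in the KO-labelled cells (log2 ratio of KO-labelled over WT-labelled -0.21, interval -0.24 to -0.18). In interstitial macrophages Plaur was at 443 and 95.1 CPM (log2 ratio -2.22, interval -2.37 to -2.07), in alveolar macrophages at 318 and 91.1 CPM (log2 ratio -1.80), and in neutrophils at 2070 and 1255 CPM (log2 ratio -0.72). Classical monocytes were at 1166 and 598 CPM, plasma cells at 183 and 149 CPM, and CCR7 dendritic cells, a migratory state, at 82.6 and 45.8 CPM. Several lymphoid and myeloid classes had more Plaur in the KO-labelled library. NK cells held 5 Plaur UMIs in the WT-labelled and 156 in the KO-labelled library (log2 ratio 4.62, interval 3.37 to 6.26), or a log2 ratio of 2.32 with doublet calls kept. T cell clusters 14, 15 and 18 had log2 ratios of 2.78, 5.16 and 4.81. B cells were at 203 and 307 CPM (log2 ratio 0.60, interval 0.46 to 0.74), cDC1, which cross-present antigen, at 11.4 and 48.3 CPM (log2 ratio 2.08, interval 1.40 to 2.83), and nonclassical monocytes at 276 and 572 CPM. In cDC2, dendritic cells that present antigen to CD4 T cells, the interval of the log2 ratio of 0.22 included 0 (-0.016 to 0.46), and the ratio was 0.089 with thinned cells and 0.35 without the 5 cells per library with most Plaur UMIs. Plaur lies on chromosome 7 at 24460937 to 24475970 of the mm10 build. A 3′ tag can lie outside the part removed in the knockout, so its level checks nothing about the labels.

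**Figure D1:**
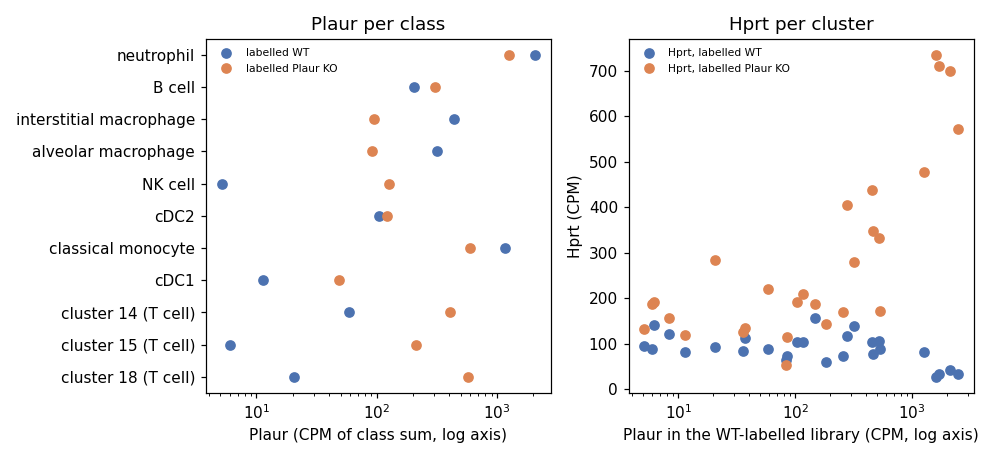
Left, Plaur in CPM of the class sum (log axis) per class or T cell cluster and library; right, Hprt in CPM against Plaur CPM in the WT-labelled library (log axis), 1 point per cluster and library. Plaur in interstitial macrophages was at 443 CPM in the WT-labelled and 95.1 CPM in the KO-labelled library, and Hprt reached 735 CPM in a neutrophil cluster of the KO-labelled library.

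The make-up of the sorted cells addressed which leukocytes were in the challenged lung with and without uPAR. The labels describe the sorted cells both as circulating leukocytes and as a whole-lung lysate, so which leukocytes the gate let through, and hence what a share covers, is not clear. Classical monocytes, which enter inflamed tissue from blood, made up 2.82% of the WT-labelled cells (245 cells, interval 2.48% to 3.19%) and 8.63% of the KO-labelled cells (827 cells, interval 8.07% to 9.21%). Neutrophils made up 26.2% and 34.6% (1.32-fold, interval 1.25 to 1.39), and NK cells 3.65% and 4.89% (1.34-fold, interval 1.16 to 1.55). Shares were lower in the KO-labelled library for alveolar macrophages, the resident phagocytes of the air spaces, at 11.6% and 6.37% (0.550-fold, interval 0.497 to 0.609), for B cells at 17.2% and 11.7% (0.681-fold, interval 0.630 to 0.736), and for interstitial macrophages at 9.29% and 7.34% (0.790-fold, interval 0.713 to 0.875). The interval of the ratio included 1 for cDC2 (1.13-fold, interval 0.966 to 1.32) and for cDC1 (1.19-fold, interval 0.978 to 1.45). Shares of a library add up to a fixed total: among cells other than neutrophils the log2 ratio of interstitial macrophages went from -0.34 to -0.17. The classical monocyte difference was smaller when cells were clustered without genes near Plaur, Hprt and interferon genes. Their clusters then held 164 and 185 WT-labelled and 229 and 653 KO-labelled cells, against 60 and 185 and 177 and 650 in the main clustering. The change thus lay in the smaller cluster, and no cluster stayed unnamed in that setting. The unnamed cluster 28 of the main clustering held 100 WT-labelled and 59 KO-labelled cells. Which cells joined the monocytes was not examined, so the smaller difference does not show an influence of the genes left out. Other clusterings put CCR7 dendritic cells into the cDC2 class, and with both pooled the log2 ratio was 0.063, or -0.13 at the coarser clustering, where unnamed and plasmacytoid dendritic cells joined them, and 0.092 with each library clustered alone, with intervals that included 0.

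Among smaller classes, nonclassical monocytes, which patrol vessels, made up 0.887% and 1.42% (1.60-fold, interval 1.20 to 2.14), and gamma-delta T cells 0.979% and 0.657% (0.671-fold, interval 0.477 to 0.941). Group 2 innate lymphoid cells, a source of type 2 cytokines, made up 0.668% and 0.793% (1.19-fold, interval 0.832 to 1.70). Other clusterings joined these innate cells with gamma-delta T cells in 1 or both libraries, and the classes pooled were at a log2 ratio of -0.18, or -0.18 at the coarser clustering and -0.15 with each library clustered alone, with intervals that included 0. Regulatory T cells were joined with cells of T cluster 15 there, 119 in the WT-labelled and 290 in the KO-labelled library when each was clustered alone, so the shares do not compare across clusterings. The intervals included 1 for regulatory T cells, CCR7 dendritic cells, plasma cells and plasmacytoid dendritic cells. T cells were compared by cluster, because a cluster of them, number 9, had more NK cell than T cell markers among its leading genes. Cluster 9 made up 2.88% and 1.46%, cluster 14 4.35% and 3.25%, cluster 15 3.95% and 3.17%, and cluster 18 3.49% and 3.08%. Among cells other than neutrophils the log2 ratios of clusters 14, 15 and 18 were -0.25, -0.14 and -0.0079, against -0.42, -0.32 and -0.18 among all cells.

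**Figure D2:**
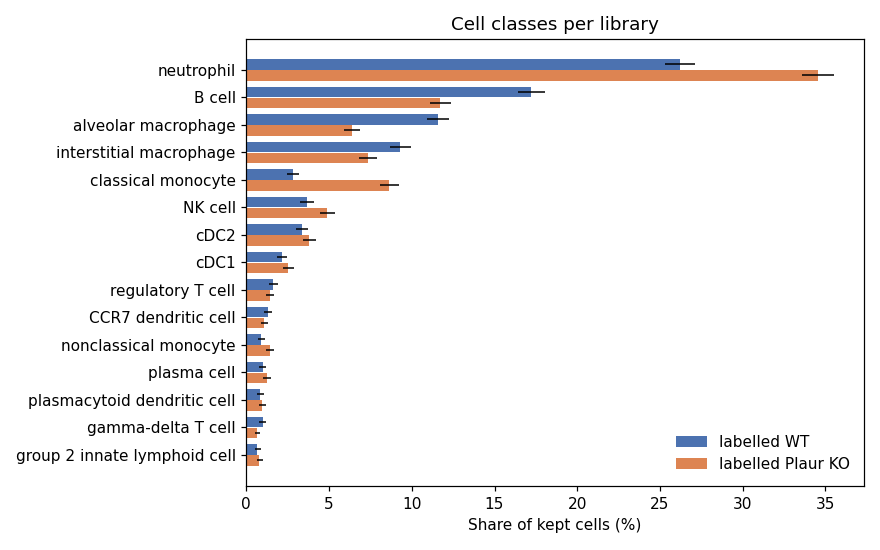
Share of kept cells (%) per named class in the WT-labelled and the KO-labelled library, 1 library each; bars start at 0 and lines are exact binomial intervals that cover counting error only. The classical monocyte share was 2.82% in the WT-labelled and 8.63% in the KO-labelled library.

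Eosinophils, the cells in the title of the series, formed no cluster in either library. No barcode carried at least 3 of 7 eosinophil genes (Ccr3, Il5ra, Epx, Prg2, Prg3, Ear6 and Alox15) among 9024 WT-labelled and 10102 KO-labelled barcodes, which allows shares of up to 0.0332% and 0.0297% for such barcodes. Epx, the eosinophil peroxidase, had 0 UMIs in both. The deposited barcodes held at least 501 UMIs in the WT-labelled and 500 in the KO-labelled library, so cells with less RNA could not be seen and eosinophils in the tissue could not be assessed.

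In neutrophils, type I interferon response genes were higher in the KO-labelled library and inflammatory cytokine genes were lower. Of 43 measured interferon genes 39 were higher, with a median log2 ratio of 0.58, above the central 95% of random lists of equal size and expression (-0.12 to 0.068). Ifit1, which binds viral RNA, was at 25.1 and 72.6 CPM (log2 ratio 1.53, interval 1.26 to 1.81) and Ifit3b at 8.49 and 30.1 CPM (log2 ratio 1.82). With each cluster weighted alike Ifit1 was at 0.86, Ifit3b at 0.44 and the list at 0.48. The interferon-led cluster 32 enters these weighted values with only 9 WT-labelled cells. Of 33 NF-kB and cytokine genes 28 were lower (median -0.48, random lists -0.14 to 0.084, or -0.26 with each cluster weighted alike). Ptgs2, the inducible cyclooxygenase, was at 1357 and 568 CPM (log2 ratio -1.26, interval -1.31 to -1.20) and the cytokine Tnf at 115 and 52.6 CPM, while Cxcl3, a neutrophil attractant, was at 239.6 and 412 CPM. Of 35 immediate early genes 25 were lower (median -0.26, random lists -0.13 to 0.082), among them Nr4a3, a nuclear receptor, at 114 and 29.4 CPM. Of 24 granule genes 17 were higher (median 0.17), which became -0.053 with each cluster weighted alike. TMM and DESeq2 factors moved every neutrophil log2 ratio, those of random lists included, by 0.11 and 0.12, which leaves the place of a list among random lists as it is. Cluster 32, led by interferon response genes, held 9 WT-labelled and 138 KO-labelled cells. Clusters 8, 11 and 4 held most WT-labelled and clusters 11, 19 and 8 most KO-labelled neutrophils.

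By size, the neutrophil genes with the highest ratios were Ccl1, Hprt, Irgc1, Ifit3b, Ifit1 and Wfdc17. Hprt, a purine salvage enzyme, was at 37.3 and 689 CPM (log2 ratio 4.21, interval 4.00 to 4.42), Irgc1, encoded at 24431919 to 24445682 on the chromosome of Plaur, at 12.7 and 72.3 CPM (interval of the log2 ratio 2.14 to 2.89), and Wfdc17 at 1087 and 2663 CPM (log2 ratio 1.29, interval 1.25 to 1.33). Ccl1, a chemokine, had 230 UMIs, all in 2 KO-labelled cells, and 0 in WT-labelled neutrophils. The lowest were Nrg1, Nr4a3, Gm16174, Rasgef1b, Tagap and Flt1, with log2 ratios from -2.34 for Nrg1 to -1.58 for Tagap. RNA of lymphocytes was lower in KO-labelled neutrophils for some lists: of 12 cytotoxic genes 12 were lower (median -1.08), and T cell genes had a median of -0.87, or -0.32 with doublet calls kept and -0.49 with each cluster weighted alike. Igkc, an immunoglobulin chain of B cells, was at 53.4 and 49.3 CPM, complement and macrophage scavenging genes were higher in 8 and lower in 8 of 16 cases, and lung epithelial genes were higher in 4 of 5. Apoe, a lipoprotein of macrophages that was lower in the whole KO-labelled library (1893 and 301 CPM), was at 137 and 4.28 CPM in neutrophils. MHC class II genes had a median of -0.35 (13 of 14 lower), or -0.21 with each cluster weighted alike, and interferon-gamma response genes one of -0.18, which became 0.032 with each cluster weighted alike.

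In interstitial macrophages, type 2 axis, complement and scavenging, and MHC class II genes were higher in the KO-labelled library by their medians. With each cluster weighted alike these medians went to 0.025, 0.0098 and -0.0069. The libraries also differed in the clusters that made up this class and in RNA of other cell types. Cluster 10, led by Gpnmb, Trem2 and Apoe, held most WT-labelled cells and cluster 12, led by Ccl12, Ccl8 and C1qa, most KO-labelled cells. Of 15 type 2 axis genes 11 were higher (median 0.54, random lists -0.16 to 0.16), which became 0.025 with each cluster weighted alike. Arg1, the arginase of alternatively activated macrophages, was at 30.9 and 148 CPM (log2 ratio 2.26, interval 2.03 to 2.49) and the cytokine Il10 at 12.1 and 29.6 CPM, while Retnla was at 73.4 and 34.1 CPM. Of 29 complement and scavenging genes 18 were higher (median 0.35, 0.0098 with each cluster weighted alike), with the mannose receptor Mrc1 at 826 and 1666 CPM and the haemoglobin scavenger receptor Cd163 at 27.4 and 66.4 CPM. MHC class II genes had a median of 0.32, or -0.0069 weighted alike. Of 37 interferon-gamma and MHC class I genes 24 were lower (median -0.18, random lists -0.069 to 0.10), with the transcription factor Irf1 at 314 and 181 CPM. Plasminogen system genes had a median of -0.21, or -0.033 weighted alike, with the macrophage elastase Mmp12 at 195 and 441 CPM. Of 47 type I interferon genes 31 were lower (median -0.11, random lists -0.10 to 0.071), with a median of -0.23 weighted alike and -0.031 with thinned cells. Of 13 cytotoxic genes of lymphocytes 11 were higher (median 0.37, 0.22 weighted alike). Of 37 immediate early genes, which also respond to tissue digestion, 27 were higher (median 0.16, random lists -0.079 to 0.098, 0.28 with thinned cells and 0.062 weighted alike). Of 17 granule genes of neutrophils 13 were lower (median -0.34), with -0.53 in thinned cells, -0.11 weighted alike and 0.12 with doublet calls kept.

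The interstitial macrophage genes with the highest ratios were Gm21860, H2-M2, Apol7c, Hbegf, Edn1 and Mt2, and the lowest were Apoc2, Plaur, Apoe, Cstdc4, Mirt1 and Cass4. Cstdc4 and Cass4 were also among the leading genes of neutrophil cluster 4. Whether their counts here came from neutrophil RNA was not tested. Apoe was at 10466 and 2637 CPM (log2 ratio -1.99, interval -2.02 to -1.96) and Apoc2, its neighbour on chromosome 7, at 40.7 and 1.11 CPM (log2 ratio -5.20, interval -6.83 to -3.96). Hbegf, a ligand of the EGF receptor, was at 82.2 and 256 CPM and Mt2, a metallothionein, at 84.2 and 236 CPM. With each cluster weighted alike the log2 ratio of Hbegf went from 1.64 to 1.02, of Mt2 from 1.49 to 0.74 and of Apol7c from 1.92 to 1.07, or to 1.17 with thinned cells. With doublet calls kept Apoc2 was at -3.41, Cstdc4 at -0.65, Mirt1 at -0.98 and Cass4 at -0.72, against -5.20, -1.84, -1.74 and -1.22. With thinned cells Cstdc4, Mirt1 and Cass4 were at -1.07, -0.79 and -0.56, and Cstdc4 was at -2.84 without the 5 cells per library with most of its UMIs.

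In alveolar macrophages, immediate early genes were higher and interferon-gamma response genes lower in the KO-labelled library. Of 36 immediate early genes 29 were higher (median 0.44, random lists -0.084 to 0.067), with Jun, a subunit of the AP-1 transcription factor, at 143 and 337 CPM (log2 ratio 1.24, interval 1.12 to 1.35) and Fosb, another subunit, at 61.9 and 143 CPM (log2 ratio 1.21, interval 1.03 to 1.39). These genes also respond to tissue digestion. Of 37 interferon-gamma and MHC class I genes 33 were lower (median -0.21), which became -0.047 with each cluster weighted alike. Of 46 type I interferon genes 31 were lower (median -0.18), and the median was 0.087 with doublet calls kept, -0.31 with thinned cells and -0.037 with each cluster weighted alike. Type 17 axis genes had a median of 0.36, or 0.036 with members of 1 UMI, with the neutrophil attractants Cxcl1 at 32.1 and 55.5 CPM and Cxcl2 at 901 and 1479 CPM. The type 2 median was 0.28 (10 of 11 higher), with Mrc1 at 1186 and 1667 CPM. Plcl1, Irgc1, Slfn4, Jun, Ifitm1 and Fosb had the highest ratios, and Apoc1, Ptgir, Plaur, Srxn1, Colec12 and Inpp4b the lowest. The log2 ratio of Ifitm1 went from 1.64 to 0.43 with thinned cells, and that of Inpp4b from -1.44 to -0.93, to -0.88 with doublet calls kept and to -3.24 without the 5 cells per library with most of its UMIs. Apoc1 was at 31.7 and 2.56 CPM (log2 ratio -3.63, interval -4.71 to -2.73, or -5.54 without the 5 cells per library with most of its UMIs) and Ptgir, the prostacyclin receptor, at 18.6 and 1.54 CPM (log2 ratio -3.60, interval -5.07 to -2.44). Mature neutrophil genes had a median of 0.15 in these cells (-0.037 with thinned cells), granule genes 0.17 (0.44 with doublet calls kept, 0.038 with thinned cells, 0.053 weighted alike), B cell genes 0.17 (0.40 with thinned cells, 0.10 with doublet calls kept) and T cell genes -0.35 (0.16 with thinned cells). S100a9, abundant in neutrophils, was at 138 and 404 CPM, and in B cells at 47.6 and 113 CPM.

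In B cells, type I interferon response genes were slightly higher and MHC class II genes slightly lower in the KO-labelled library. Zfp36l2, an RNA-binding protein, was at 287 and 558 CPM (log2 ratio 0.96, interval 0.85 to 1.07), and Gm43305, Ide, Zfp36l2, Hprt, Gm15472 and Btaf1 had the highest ratios. Slc1a5, Cmss1, Rell1, Cdk8, Rbm3 and Socs3 had the lowest, with Slc1a5, a glutamine transporter encoded on chromosome 7, at 71.7 and 22.1 CPM (log2 ratio -1.70, interval -2.13 to -1.30). Of 40 type I interferon genes 29 were higher (median 0.19, random lists -0.075 to 0.13, 0.42 with doublet calls kept), and of 16 MHC class II genes 11 were lower (median -0.10, -0.033 with thinned cells). RNA of some other cell types was also higher in these B cells. Mature neutrophil genes were at 0.32 (11 of 15 higher, random lists -0.11 to 0.17) and T cell genes at 0.27 (12 of 18 higher, random lists -0.091 to 0.14), the latter 0.15 with members of at least 50 UMIs, 0.12 with thinned cells and 0.095 with members of 1 UMI. Cytotoxic genes were at 0.34 (5 of 8 higher), inside the range of random lists (-0.40 to 0.36), and immediate early genes at 0.10.

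In NK cells, cell cycle genes were higher and NF-kB genes lower in the KO-labelled library. Of 20 cell cycle genes 17 were higher (median 0.44, random lists -0.15 to 0.20), with Mki67, a marker of dividing cells, at 33.9 and 78.4 CPM (log2 ratio 1.21, interval 0.63 to 1.83). Of 18 NF-kB and cytokine genes 15 were lower (median -0.41, -0.14 with members of 1 UMI and -0.23 with thinned cells), with the adhesion molecule Icam1 at 251 and 104 CPM (log2 ratio -1.27, interval -1.59 to -0.96) and the NF-kB inhibitor Nfkbia at 342 and 175 CPM (log2 ratio -0.96, interval -1.21 to -0.71). Il1b, abundant in neutrophils, was at 15.4 and 58.2 CPM, and mature neutrophil genes had a median of 0.25 (10 of 15 higher, 0.41 with doublet calls kept). T cell genes had one of -0.14 (-0.033 with thinned cells) and immediate early genes one of -0.11 (-0.19 with thinned cells, 0.087 with doublet calls kept). Besides Plaur, the highest ratios were those of Ide, Btaf1, Dhrs3, Mfhas1 and Stk39, and the lowest those of Cmss1, Icam1, Relb, AY036118, Cdk8 and Nfkbia. The log2 ratio of Btaf1 went from 0.84 to 0.54 with thinned cells.

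In cDC2, cell cycle genes were higher in the KO-labelled library. Of 24 such genes 21 were higher (median 0.82, random lists -0.12 to 0.16, 0.46 with thinned cells), with Ube2c, a mitotic ubiquitin-conjugating enzyme, at 27.8 and 129 CPM (log2 ratio 2.22, interval 1.84 to 2.61). Of 37 immediate early genes 27 were higher (median 0.14, random lists -0.081 to 0.078), and mature neutrophil, granule, T cell, B cell and cytotoxic genes had medians of 0.10, -0.060, -0.12, -0.045 and -0.037, inside the range of random lists. Of 17 genes of eosinophil recruitment and lipid mediators 11 were lower (median -0.37, random lists -0.14 to 0.15), but the median was -0.14 with members of 1 UMI, -0.017 with doublet calls kept and -0.18 with thinned cells. Ccl6 was at 586 and 359 CPM and Ccl9 at 708 and 441 CPM, while Ccl17, an attractant of type 2 T cells, was at 2939 and 4364 CPM (log2 ratio 0.57, interval 0.53 to 0.61). Of 14 type 2 genes 9 were lower (median -0.29, -0.10 with doublet calls kept and -0.47 with members of 1 UMI), although the growth factor Areg had 2 UMIs in the WT-labelled and 52 in the KO-labelled library (interval of the log2 ratio 2.51 to 7.52). Tsc22d3, Fkbp5, Pid1, Dleu2, Hsph1 and Pacs2 had the highest ratios. Tsc22d3 and Fkbp5, both induced by glucocorticoids, were at 24.9 and 80.8 CPM and at 27.0 and 71.2 CPM. Dscam, Lyz1, Fchsd2, Cmss1, Lima1 and Plcb1 had the lowest. With thinned cells the log2 ratio of Hsph1 went from 1.21 to 2.24 and that of Lima1 from -1.32 to -0.31, or to -0.77 with doublet calls kept.

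**Figure D3:**
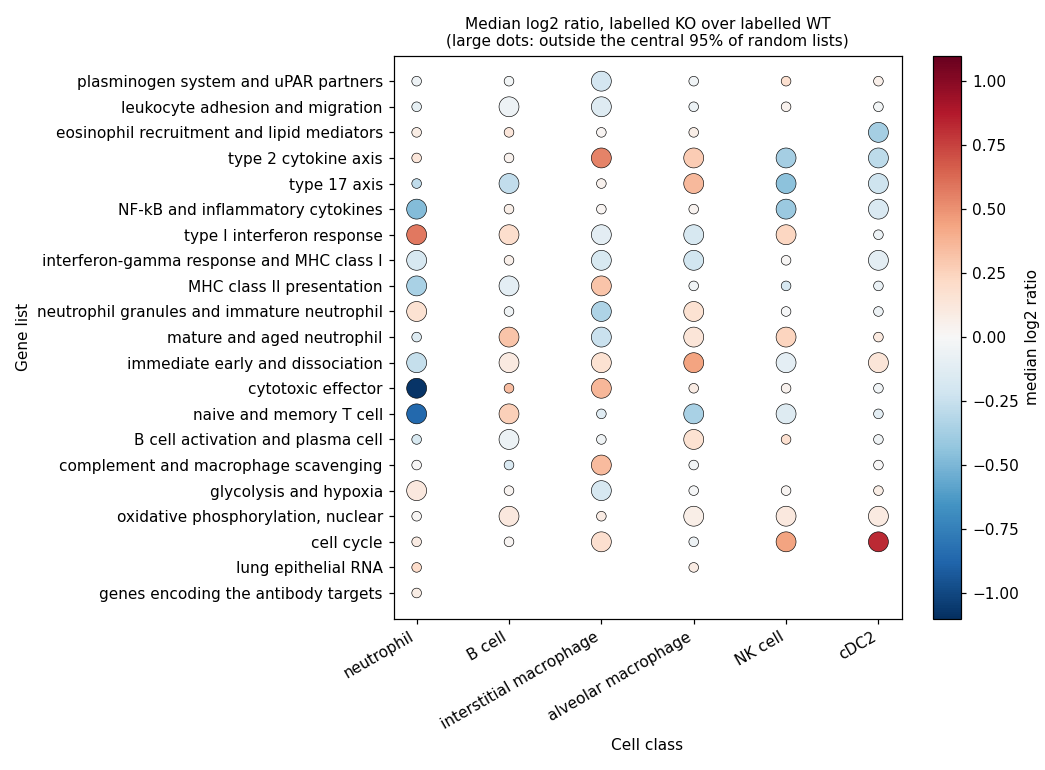
Median log2 ratio (KO-labelled over WT-labelled, colour) of each gene list per main cell class; large dots lie outside the central 95% of random lists, and blank places had under 5 measured members. The type I interferon median was 0.58 in neutrophils and -0.18 in alveolar macrophages, or 0.087 there with doublet calls kept.

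Of 115 pairs of list and class, 58 had a median outside the central 95% of random lists, against 5.8 for unrelated genes. Members of a list vary together from cell to cell, so such a position describes these libraries and is no test of the genotype. Over the main classes, medians ran from -0.21 to 0.17 for the plasminogen system, from -0.14 to 0.044 for adhesion and migration, from -0.24 to 0.32 for mature neutrophil genes, from -0.18 to 0.18 for B cell activation, from -0.19 to 0.11 for glycolysis and hypoxia, and from 0.016 to 0.11 for nuclear genes of oxidative phosphorylation. With each cluster weighted alike the interstitial macrophage medians of adhesion and of mature neutrophil genes went from -0.14 to -0.058 and from -0.24 to -0.089. For glycolysis, thinned interstitial macrophages had 0.019 in place of -0.19. Lung epithelial RNA had medians of 0.20 in neutrophils and 0.094 in alveolar macrophages, and genes encoding the antibody targets 0.085 in neutrophils.

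CD11b is an integrin chain and known partner of uPAR on myeloid cells. Relative to the B cells of each library, its surface level was lower in KO-labelled interstitial macrophages, neutrophils and classical monocytes. This did not hold for every class: in gamma-delta T cells the log2 difference was 1.30 (interval 1.16 to 1.45). That value rested largely on 1 cell, which held 654 of the 1166 CD11b UMIs of the 63 KO-labelled cells. Medians there were 3 and 4 UMIs per cell, and the difference was 0.42 with medians and 0.31 with centred log-ratios. Interstitial macrophages carried a mean of 157 CD11b UMIs per cell in the WT-labelled and 86.4 in the KO-labelled library, against 4.91 and 5.55 in B cells, a KO minus WT difference of -1.04 in the log2 ratio to B cells (interval -1.05 to -1.03). Neutrophils carried 171 and 127 (difference -0.60) and classical monocytes 378 and 339.7 (difference -0.33). Clusters 10 and 12 held 549 and 258 WT-labelled and 310 and 394 KO-labelled interstitial macrophages, and with each cluster weighted alike the differences were -0.63, -0.44 and -0.36. With centred log-ratios these differences were -0.69, -0.34 and -0.14, and with medians -1.05, -0.39 and -0.020. RNA of Itgam, which encodes CD11b, had a log2 ratio of -0.30 in interstitial macrophages, or -0.19 with thinned cells, and 0.085 in neutrophils, or 0.19 with TMM factors. Ly-6C was at 9.60 and 18.2 UMIs per cell in B cells and at 27.7 and 33.4 in neutrophils, so that its difference in neutrophils was -0.66 relative to B cells and 0.27 without a reference. ST2, the IL-33 receptor, reached 2.66 and 2.36 UMIs per cell in group 2 innate lymphoid cells against 0.776 and 0.867 in B cells. CCR3 and CD14 stayed within 2-fold of the B cell level in the main classes and in classical monocytes.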

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

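The tests on free RNA, Hprt, the interferon-led cluster, scaling and depth, and the weighting of each cluster alike, were chosen only after the results were seen. The differences between cell classes given here were not tested, since there was 1 library per genotype.

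Plaur stood out because it was lower in the KO-labelled library in some cell classes and higher in others: the log2 ratio was -0.72 in neutrophils, -2.22 in interstitial and -1.80 in alveolar macrophages, but 0.60 in B cells, 2.08 in cDC1 and 4.62 in NK cells. Free RNA from neutrophils would bring S100a8 along, and Plaur in KO-labelled NK cells and T clusters 14, 15 and 18 was at least 32.6 times the level that S100a8 predicted, with Plaur in 24.9% and S100a8 in 15.8% of KO-labelled NK cells, which argues against it. A candidate explanation is a changed Plaur locus that carries Hprt sequence, read by the 3′ tags: across 27 clusters the excess of Hprt in the KO-labelled library followed the Plaur level of the WT-labelled one (Spearman rho 0.735), while Hprt of the WT-labelled library itself did not (rho -0.437). Clusters of 1 library are not independent, and this leaves the higher Plaur in these NK, B and T cells and cDC1 itself without a tested cause. A wrong label of a library was not tested by another marker, and a response of the cells to the loss of uPAR stays open.

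Type I interferon genes stood out because their median log2 ratio was 0.58 in neutrophils and -0.18 in alveolar macrophages, or 0.087 there with doublet calls kept and -0.037 with each cluster weighted alike, while interstitial macrophages were at -0.11, or -0.23 weighted alike and -0.031 with thinned cells, and T cluster 15 was at -0.23. Medians were also positive in B cells (0.19), NK cells (0.23) and classical monocytes. More cells of the interferon-led cluster 32 cannot be the whole cause in neutrophils, since without it the median was 0.40, above random lists, with 37 of 43 genes higher. Clusters 4, 8, 11 and 19 had medians of 0.51, 0.47, 0.78 and 0.52. Those clusters can hold further interferon-led cells, however. With the KO-labelled library clustered alone, a neutrophil cluster led by Rsad2, Ifit3b and Ifit1 held 636 cells, against 138 KO-labelled cells in cluster 32. No neutrophil cluster of the WT-labelled library alone had these among its leading genes. A larger share of interferon-high neutrophils was therefore not excluded. Scaling moves random lists alike and so cannot put the list above them, with the lower of the TMM and DESeq2 medians at 0.68, and the thinned median of 0.62 argues against depth. Genotype, animal and library cannot be separated with 1 library each, so an effect of the genotype remains an untested hypothesis.

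Other lists had medians of opposite sign in different classes. Granule genes were at 0.17 in neutrophils and -0.34 in interstitial macrophages, but at -0.053 and -0.11 with each cluster weighted alike, and interstitial macrophages were at 0.12 with doublet calls kept, so the opposite sign between these classes was lost in both. Other cells went either way, with T cluster 14 at -0.53 and a positive median in classical monocytes. Immediate early genes were at 0.44 in alveolar macrophages and -0.26 in neutrophils, or -0.14 in neutrophils with DESeq2 factors, which moved all neutrophil genes by 0.12. Cytotoxic genes were at 0.37 in interstitial macrophages, or 0.22 with each cluster weighted alike, and -1.08 in neutrophils.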

How the results depend on the processing

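The alternatives with each cluster weighted alike, with the reduced gene set for clustering, with thinned list medians, with pooled classes and without the cells with most UMIs of a gene or antibody were chosen after seeing the data. No paired analysis was possible because the groups share only replicate number 1 and the results come from no test. Values are log2 ratios or differences, KO-labelled over WT-labelled, and the cause of a shift was not tested other than for the shares of cDC2, group 2 innate lymphoid and regulatory T cells. No value moved beyond its interval with at least 500 genes (106 results), at most 5% mitochondrial UMIs (19), a member minimum of 50 UMIs (58) or totals without mitochondrial, ribosomal and haemoglobin genes (87). For a list this interval is one of the median over its members, not of counting error, and it can be wide. With members of at least 50 UMIs, T cell genes in neutrophils went from -0.87 to -0.35 and interferon-gamma genes from -0.18 to -0.053. Values of the opposite sign numbered 5 of 145 with each cluster weighted alike, 4 of 160 with doublet calls kept, 7 of 145 with thinning, and 1 of 145 each with TMM and with DESeq2 factors, where it was Cd14 in neutrophils. For antibodies they were more frequent, at 12 of 30 with centred log-ratios, 13 of 30 with raw means, 4 of 23 with medians, 3 of 30 without the top cells and 1 of 30 weighted alike. For shares they numbered 3 of 15 at resolution 0.5 and 2 of 15 with each library clustered alone. Values outside the interval, of either sign, numbered 21, 18, 29, 7 and 8 in order for these first 5 alternatives, and 7 of 84 without the 5 cells with most UMIs of a gene. T cell clusters have no value where cells were clustered again. Genes of few UMIs and classes of few cells are limited by depth, and spread between animals is not measured at all.

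Among shares, leaving out neutrophils gave B cells -0.38, alveolar macrophages -0.69 and interstitial macrophages -0.17. Classical monocytes were at 1.19 when clustered without genes near Plaur, Hprt and interferon genes. Clusters named cDC2 gave -0.13 at resolution 0.5 and -0.26 with each library clustered alone, but these are not cDC2 alone: CCR7 dendritic cells made up 114 of 528 WT-labelled and 104 of 532 KO-labelled cells in the former, and 114 of 395 and 1 of 363 in the latter. With each library clustered alone cDC1 were at 0.0052.

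TMM and DESeq2 factors move all genes of a class alike, random lists included. Among gene lists in neutrophils, DESeq2 factors gave NF-kB -0.36, type I interferon 0.69, immediate early -0.14 and glycolysis 0.23. TMM factors gave type I interferon 0.68 and immediate early -0.15, and adhesion in B cells -0.096. With each cluster weighted alike neutrophils had NF-kB -0.26, interferon-gamma 0.032 and granules -0.053. Interstitial macrophages had plasminogen -0.033, type 2 0.025, immediate early 0.062 and cell cycle -0.15, and alveolar macrophages interferon-gamma -0.047. Doublet calls kept gave T cell genes in neutrophils -0.32, type I interferon in B cells 0.42 and in alveolar macrophages 0.087, and granules in interstitial macrophages 0.12. Thinning gave type I interferon -0.031, granules -0.53 and glycolysis 0.019 in interstitial macrophages, T cell genes 0.16 in alveolar macrophages, and type 17 -0.68 and NF-kB -0.41 in cDC2. With members of 1 UMI NF-kB in NK cells was -0.14.

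For antibodies, centred log-ratios gave CD11b -0.34 in neutrophils, -0.13 in alveolar macrophages, -0.69 in interstitial macrophages, -0.14 in classical monocytes and -0.075 in cDC2. In that order without cDC2, Ly-6C was -0.30, 0.051, 0.12 and -0.33. CCR3 was 0.21 in neutrophils, 0.028 in alveolar and 0.22 in interstitial macrophages, CD14 0.016 in alveolar macrophages and 0.096 in classical monocytes, and ST2 0.17 in neutrophils. Medians gave CD11b -0.39 in neutrophils, 0.00 in alveolar macrophages, -0.020 in classical monocytes, 0.14 in NK cells and 0.14 in cDC2, and Ly-6C -0.43 in neutrophils, -0.12 in interstitial macrophages, -0.49 in classical monocytes and 0.096 in cDC2. Raw means, in neutrophils, alveolar macrophages, interstitial macrophages, classical monocytes, NK cells and cDC2, gave CD11b -0.43, -0.088, -0.86, -0.15, 0.10 and -0.15, and Ly-6C 0.27, 0.85, 0.56, 0.67, 0.86 and 0.88. Raw ST2 in neutrophils was 0.056 and raw CD14 in NK cells -0.11. With each cluster weighted alike CD11b was -0.44 in neutrophils, -0.40 in alveolar macrophages, -0.63 in interstitial macrophages and -0.36 in classical monocytes, and Ly-6C -0.59 in neutrophils and -0.32 in interstitial macrophages. Without the 1% of cells with most UMIs, CD11b was -0.17 in alveolar macrophages, -1.07 in interstitial macrophages, -0.34 in classical monocytes and -0.28 in cDC2, and Ly-6C -0.63 in neutrophils, -0.23 in interstitial macrophages and -0.57 in classical monocytes.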

Other observations

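The expression of classical monocytes was examined after their share was seen, and the test of passenger DNA was chosen after the result was seen. In classical monocytes, nuclear genes of oxidative phosphorylation were higher in the KO-labelled library in 40 of 40 cases (median log2 ratio 0.40, random lists -0.15 to 0.13). Of 49 type I interferon genes 40 were higher (median 0.31), and of 34 NF-kB and cytokine genes 27 were lower (median -0.56, random lists -0.17 to 0.14). Ptgs2, the inducible cyclooxygenase, was at 545 and 180.2 CPM (log2 ratio -1.60, interval -1.70 to -1.50). Immediate early genes had a median of -0.45 and interferon-gamma response genes one of -0.31. RNA of lymphocytes was lower in the same class, with 17 of 19 cytotoxic genes (median -0.71, random lists -0.32 to 0.23) and 17 of 21 T cell genes (median -0.65, random lists -0.29 to 0.21) lower. Of 16 genes of eosinophil recruitment and lipid mediators 12 were higher (median 0.42, random lists -0.25 to 0.22), among them Ccl24, an eosinophil attractant, at 26.0 and 83.5 CPM (log2 ratio 1.68, interval 1.31 to 2.07). Retnla, a product of alternatively activated macrophages, was at 1.22 and 18.8 CPM (log2 ratio 3.94, interval 2.37 to 6.23). Hprt was at 85.0 and 473 CPM and Irgc1 at 13.8 and 56.5 CPM. Granule genes had a median of 0.38, with the granule gene Ngp from 2 WT-labelled and 37 KO-labelled cells.

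Several genes with extreme ratios lie within 10 Mb of Plaur, among them Slc1a5, Ptgir, Fosb, Relb, Apoc2, Apoc1 and Apoe, and Apoe over all kept cells was at 1893 and 301 CPM. A hypothesis is passenger DNA beside the targeted locus, from another strain, which could change the level or the counting of neighbouring genes. Without Plaur and Irgc1, the mean absolute log2 ratio of this window lay above the 95th percentile of windows of equal size in 3 of 6 main classes, at percentiles of 98.3 in B cells, 99.3 in interstitial and 100 in alveolar macrophages, but of 87.9 in neutrophils, 91.0 in cDC2 and 42.1 in NK cells. This lies between the bounds set for and against the hypothesis, so it stays open. The genes that prompted the hypothesis were left in the window and can raise its percentiles, so high percentiles are no independent support. The shift between clusters within classes is argued against as the cause, since with each cluster weighted alike the window stayed above that percentile in 3 classes.

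The KO-labelled library held 19 epithelial cells and the WT-labelled 4, despite the CD45.2 sort. Scgb1a1, a secretory cell gene, was at 846 and 2638 CPM over all kept cells, and at 37.3 and 32.6 CPM outside the epithelial cells.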
